A study of Mus musculus with 12 samples.

How the data were processed

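RNA was measured in 12 libraries of naive CD4 T cells, 4 sorted populations from each of 3 untreated mice. Per the labels' protocols, cells were sorted by flow cytometry into lysis buffer, RNA was purified with the Quick-RNA MicroPrep kit, and polyadenylated RNA was turned into cDNA with the SMART-seq v4 kit and into libraries with the NexteraXT kit. The submitters' processing notes name the aligner STAR and the genome builds mm9 and mm10, with no version or role. The counting tool, the annotation, strand use in counting and the rule for listing a gene are not given in the sources used here. Because both builds are named and the table holds no positions, no coordinates are printed.

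The authors deposited 1 table of RPKM values (reads per kilobase of gene length per M reads, M standing for mega) with a column per library and 10073 genes, each with an Entrez identifier and a length, 3 of them without a symbol. Per the file headers the values are RPKM, which are not counts, so the tests were made on a log scale. RPKM multiplied by length and by a library's depth gave whole reads, within 0.1 read, for 100.0% of the values examined in every library (7604 to 8497 values). The depth so recovered was 6.31 (A3) to 9.07 (C1) M reads, and the listed genes held 99.07% (C3) to 99.71% (C2) of them. The 10 most abundant genes took 3.2% to 3.6% of reads. The steps were used for depth and for 1 added alternative, and 7 values in the table were 0. The depth recovery was tested on simulated data for 3 depths, where 100.0% of reads came out exact.

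Populations and mouse numbers came from the labels. Genes with a mean of at least 0.5 RPKM over the 12 libraries were tested (10021). The test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(RPKM + 0.5), fitted to all 12 libraries with no block. Fold changes are on that scale, which understates the change of low genes. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with 0.05 as the threshold. There were 6 pairwise comparisons, an F test over the 4 populations, and a test of the difference between the D minus C and the B minus A steps. In all, 28 gene lists (21 pathway and 7 marker lists), fixed before the data were examined, were tested by camera with a preset correlation of 0.01, with an estimated correlation and fry as alternatives, and their members were also counted when adjusted over the list alone. Sort markers were compared between gates by two-sided exact permutation tests of mean log2 RPKM, 5 in the family. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and statmod 1.5.0 in R, were used for the rest.

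The labels give each library a mouse number, so libraries with 1 number are stated to come from 1 animal. Checked on deviations from the population means, same-numbered libraries had a mean correlation across genes of -0.072 (range -0.613 to 0.379, 1 of 18 pairs over 0.1), against 0.032 for libraries of different number, and 2 of 12 libraries correlated best with their own number. The block was therefore fitted as an alternative, as planned.

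Genes were named by a rule fixed before the data were examined. The sort checks Nr4a1, Ly6c1, Ly6c2, Foxp3, Cd44 and Cd4 are given, of which Ly6c2 was not analysed here. Of the genes due under the rule, 1 sort check and 1 list member are not reported here. Between D and A the 10 largest changes in each direction, and in other comparisons the 5 largest, were taken among genes past the threshold, with the same sign in all 3 mice and at least 2 RPKM in the higher population, leaving out symbols that are clone or predicted-gene names. From each list up to 4 members past the threshold, or up to 2 given as values, were named by smallest p, and for the difference of steps up to 5 genes in each direction. The rule was applied likewise to the fits of 6 libraries, taking 10 in each direction there, with list members named from those fits for D against C. Other genes are said to have been named after their values were seen, and so were Jchain, Cd74, Mki67 and Hbb-bs, given for single libraries.

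The alternatives were pseudocounts of 0.1 and 1, no filter and a filter of 5 RPKM, median rescaling, quantile normalization, fits of the 6 libraries compared alone, the mouse number as a fixed or random block, no trend, robust moderation, an absolute log2 fold change of at least 1, and leaving out each library in turn. Those chosen after seeing the data were leaving out each library of the populations not compared, leaving out A1 and B1, leaving out A1, B1 and C3, limma-voom on the recovered reads, and removing a trend in transcript GC content and length from each library. GC content came from the longest GENCODE M21 transcript of each symbol, found for 9846 of the genes tested (98.3%). Planned count-model tests on the recovered reads were not run, because the deposited unit is RPKM.

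The limma step was tested on simulated data for D against A, with 200 of 10021 genes changed in each of 10 simulations. With 12 libraries it found 72.4% of genes changed by 0.5 on the log2 scale, 95.7% of those changed by 1 and 99.4% of those changed by 2, with 5.5% false calls. With 6 libraries the shares were 62.1%, 93.7% and 99.2%, with 4.9% false calls. Camera called 10 of 10 simulated lists that were shifted and 0 of 10 that were not. The simulated noise was drawn for each gene on its own. These shares therefore do not cover genes that move together, outlying libraries or trends between libraries.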

Results

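The series holds 12 RNA-seq libraries of naive CD4 T cells from 3 untreated mice, made to ask how basal T cell receptor (TCR) signalling relates to gene expression in cells that have not met a foreign antigen. The mice carried a Nur77-GFP transgene, in which regulatory sequence of Nr4a1 drives GFP. Nr4a1 is an immediate early gene that TCR signalling induces, so GFP reads recent signal strength. The mice also carried a Foxp3 reporter, used to leave out regulatory T cells. Cells of spleen and lymph nodes that were negative for the Foxp3 reporter and low in CD44 were sorted by flow cytometry into 4 populations, each from 3 mice. Population A was GFP low and Ly6C positive, B was GFP intermediate and Ly6C positive, C was GFP intermediate and Ly6C negative, and D was GFP high and Ly6C negative. Ly6C is a surface protein that is higher on naive cells with weak basal signalling. A library is named by its population and mouse number, so that A1 is population A of mouse 1. The depth recovered from the values ran from 6.31 M reads (A3) to 9.07 M reads (C1), and 10021 genes with a mean of at least 0.5 RPKM were tested.

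The transcripts of the sort markers did not follow the labelled gates in every library, so populations are called the libraries labelled A, B, C or D. Nr4a1 (Entrez 15370) stood at 35.5 ± 19.2 RPKM in the libraries labelled A, 58.0 ± 19.5 in B, 26.02 ± 2.48 in C and 63.7 ± 4.61 in D (mean ± SD, n = 3 each). The spread within A and B came from mouse 1. Nr4a1 was 57.7 RPKM in A1 against 26.1 in A2 and 22.9 in A3, and 35.97 in B1 against 73.3 in B2 and 64.6 in B3. Libraries labelled GFP intermediate (B and C) were not told apart from those labelled GFP low (A) by Nr4a1 (1.17-fold as a ratio of geometric means, two-sided exact permutation p = 0.524, n = 6 and 3), nor was GFP high (D) from GFP intermediate (1.68-fold, exact permutation p = 0.19, n = 3 and 6). Ly6c1 (Entrez 17067), one of the genes that encode Ly6C, was 54.2 ± 12.9 RPKM in the 6 libraries labelled Ly6C positive and 54.0 ± 12.1 in the 6 labelled Ly6C negative (exact permutation p = 0.989). By labelled mouse number, Nr4a1 was higher in D than in C and than in A, and in B than in C, in 3 of 3 mice, and higher in A than in B in 1 of 3. Ly6c1 was higher in A than in D, in A than in B, in C than in D and in C than in B in 3 of 3. These 5 exact tests, which include Ly6a (p = 0.548) and Ly6e (p = 0.496), had Benjamini-Hochberg adjusted values from 0.685 to 0.989. They took libraries as independent, although each mouse number gave a library to every population, so n counts libraries and not animals. Ly6c2 was not analysed here. Of the other sort checks, Cd4 ranged from 226 ± 2.30 RPKM in D to 241 ± 12.7 in C and Cd44 from 6.46 ± 0.819 in B to 9.09 ± 3.24 in C. Foxp3, the regulatory T cell factor, ranged from 1.36 ± 0.090 RPKM in C to 3.67 ± 0.381 in D.

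**Figure D1:**
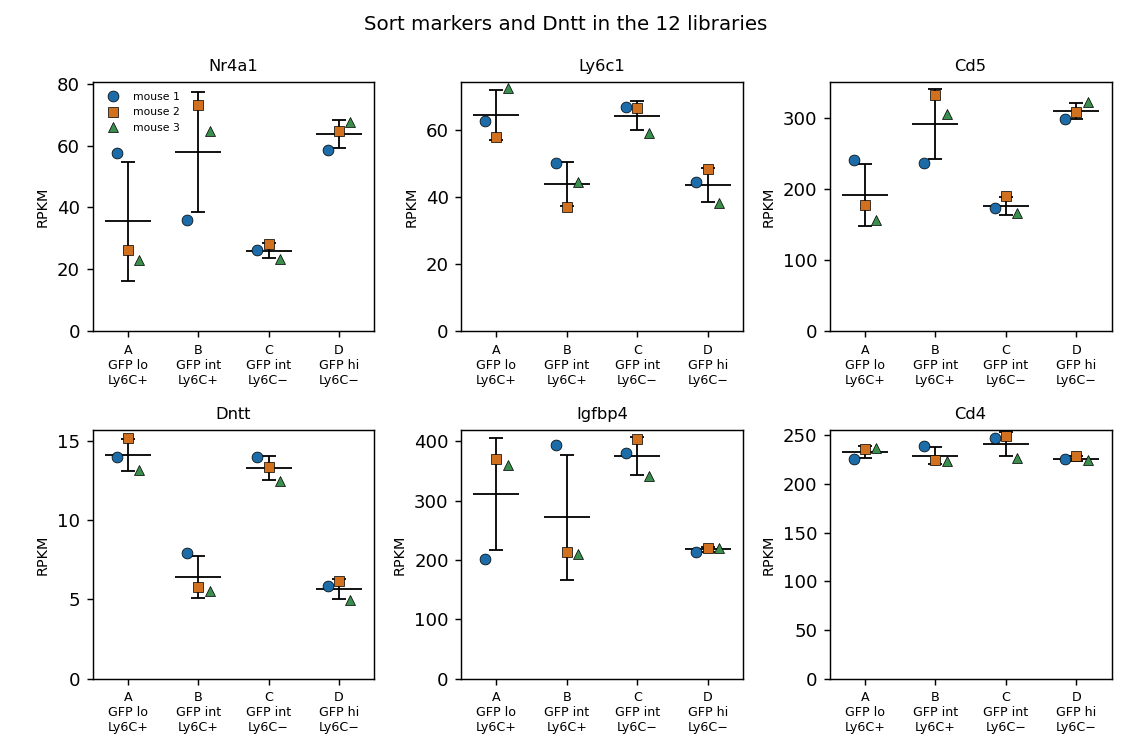
Transcript level (RPKM, linear axis from 0) of Nr4a1, Ly6c1, Cd5, Dntt, Igfbp4 and Cd4 in the 12 libraries by labelled population. Symbols are single libraries coded by mouse, and bars are the mean ± SD of 3 libraries. Nr4a1 is 57.7 in A1 and 35.97 in B1, apart from the other libraries of A and B.

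The first principal component, 40.3% of the variance, also set mouse 1 of A and B apart. Scores were 8.08 in A1, 13.8 in B2 and 12.1 in B3, and between 10.95 and 12.8 in the 3 libraries labelled D. All other libraries lay below 0, from -9.41 (B1) to -13.5 (A3). The second component, 22.8% of the variance, separated C3 (-27.2) from the rest. C3 held 709 RPKM of Jchain, the joining chain of secreted antibodies, against 0.515 to 6.33 RPKM elsewhere, 209 RPKM of the MHC class II chaperone Cd74 against 3.12 to 19.7, and 17.0 RPKM of the proliferation marker Mki67 against 0.550 to 3.27.

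**Figure D2:**
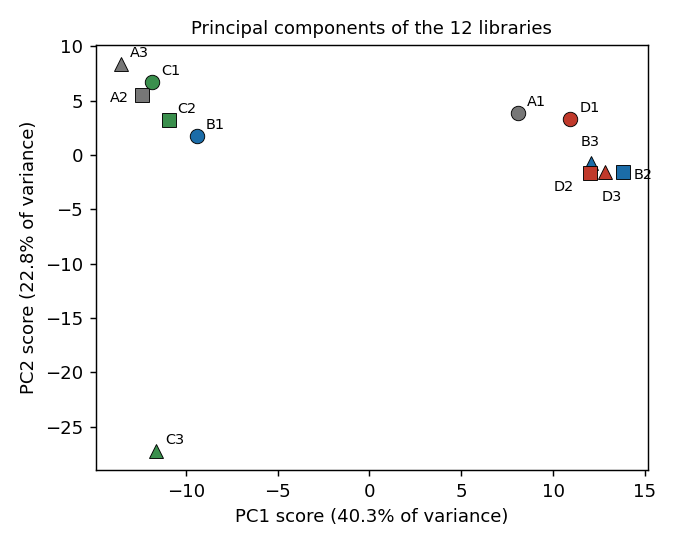
Scores of the 12 libraries on the first 2 principal components of log2(RPKM + 0.5), with the share of variance on each axis. Colours are labelled populations and symbols are mice. A1 (8.08) and B1 (-9.41) lie on the opposite side of 0 from the other libraries of A and B, and C3 lies at -27.2 on the second component.

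Comparing D with C sets GFP high against intermediate among cells labelled Ly6C negative. Ly6c1 was higher in C than in D in 3 of 3 mice, so this pair does not set signal strength apart from Ly6C level. In the fit of all 12 libraries, 1 of 10021 genes passed an adjusted p of 0.05. This was Dntt (Entrez 21673), which encodes the terminal transferase that adds nucleotides during antigen receptor rearrangement and fell by 1.16 ± 0.12 on the log2 scale (± SE), from 13.3 ± 0.761 RPKM in C to 5.65 ± 0.606 in D (adjusted p = 0.00404). At an unadjusted p under 0.05 there were 1817 genes. With 1 library of the other populations left out, 288 genes passed without A1 and 398 without B1, and 1 without A2, A3, B2 or B3. Fitted on the 6 libraries compared alone, a choice made before the data were examined that leaves A1 and B1 out of the estimate of spread, 481 genes passed, 336 higher and 145 lower in D. The values of all 3 libraries of D lay outside those of C in 24% of genes tested, where chance gives 10% on average over splits. The share was 29.2% for B and A, 25.8% for D and A, 17.9% for C and A, 15.1% for C and B and 11% for D and B. It is therefore not particular to this pair. The largest increases in that fit were in Eomes (log2 fold change 3.56 ± 0.13), a T-box factor of effector and memory cells, Tnfrsf9 (3.47 ± 0.11), a costimulatory receptor induced by TCR signals, and Myb (3.40 ± 0.08), a transcription factor. Lag3 (2.95), Arhgap20 (2.74), Ikzf2 (2.47), Cldn10 (2.43), Rgs16 (2.43), Tnfsf11 (2.40) and Pdcd1 (2.23) followed. After Dntt, the largest decreases were in Adamts14 (-0.93 ± 0.09), Pdlim4 (-0.83 ± 0.10), Igfbp4 (-0.78 ± 0.06) and Il7r (-0.76 ± 0.08), the survival cytokine receptor of naive cells, followed by Nacc2 (-0.75), Snord104 (-0.71), Gbp11 (-0.68), Lrrc75b (-0.68) and Ifi30 (-0.64).

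The gene lists fixed in advance gave the same fit of 6 libraries more detail. Of 33 measured genes of the TCR-induced early response, 15 were higher in D and 1 lower, among them Nr4a1 (log2 fold change 1.28), Spry1 (2.13), Nr4a3 (1.46) and Cd5 (0.81), with Cd40lg lower (-0.37). Of 16 inhibitory receptors, 8 were higher and 1 lower. The highest by adjusted p were Pdcd1 (2.23), Cd200 (1.93), Lag3 (2.95) and Cd5, and Lair1 was lower (-0.62). Of 23 genes associated with anergy, a state of reduced responsiveness after antigen encounter, 18 were higher and 0 lower, including Ikzf2, Ikzf4 (1.61) and Izumo1r (1.35). Of 19 T follicular helper genes, 15 were higher, including the lineage factor Bcl6 (1.45) and the follicle-homing receptor Cxcr5 (1.34), and Il6ra was lower (-0.32). Of 16 regulatory T cell genes, 11 were higher and 0 lower, including Foxp3 (1.16) and Tnfrsf9. Of 41 intracellular negative regulators of TCR signalling, 10 were higher, with Spry1, Dgkz (0.57) and Ptpn22 (0.36) leading, and 3 lower, Socs3 (-0.43), Sla2 (-0.37) and Sit1 (-0.40). Cd40lg, Lair1, Il6ra, Socs3, Sla2 and Sit1 are named as the members that moved against the rest of their list, after their values were seen. Cytokine receptors and JAK-STAT mediators split into 5 higher, led by Il2rb (1.95) and Il6st (0.61), and 4 lower, led by Il7r, of 28. Igfbp4, Il7r and Itgb7 (-0.27) were the 3 of 25 naive-state and homing genes that were lower, and 0 were higher. Of 76 cytosolic ribosomal protein genes, 13 were lower and 0 higher, with small changes such as Rps16 (-0.25) and Rpl5 (-0.20). In this limma fit 0 of 70 oxidative phosphorylation and 0 of 18 glycolysis genes passed.

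**Figure D3:**
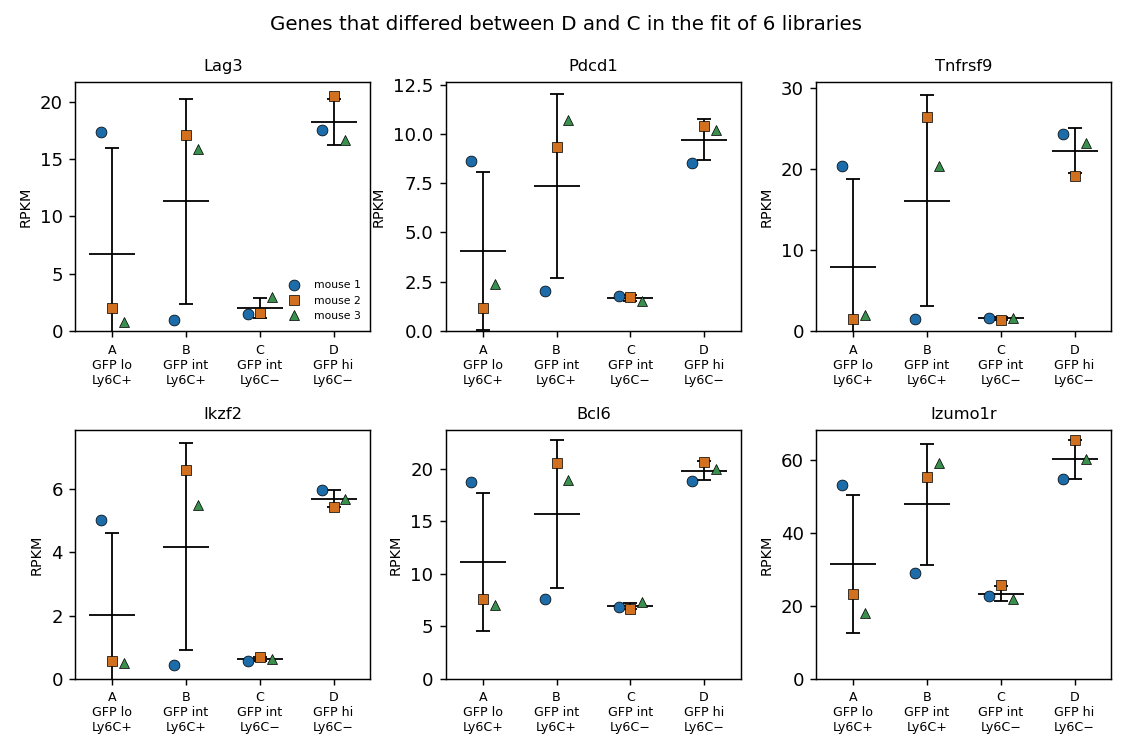
Transcript level (RPKM, linear axis from 0) of Lag3, Pdcd1, Tnfrsf9, Ikzf2, Bcl6 and Izumo1r in the 12 libraries by labelled population. Symbols are single libraries coded by mouse, and bars are the mean ± SD of 3 libraries, with the lower bar ending at the axis where the SD exceeds the mean. All 3 libraries of D lie above all 3 of C, while A1 is high and B1 is low within their populations (Tnfrsf9 20.4 and 1.43 RPKM).

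Adjusted over the list alone, the fit of 12 libraries gave 15 higher and 3 lower for the TCR-induced early response, 9 and 2 for inhibitory receptors, 17 and 0 for anergy, 15 and 1 for T follicular helper, 12 and 0 for regulatory T cell, 10 and 5 for negative regulator, 9 and 5 for cytokine receptor and 1 and 3 for naive-state genes. Of the 76 ribosomal protein genes 0 passed that way in limma, against 13 in the fit of 6 libraries over all genes and 61 in that fit over the list alone. Set against all other genes by camera with a preset correlation of 0.01, the anergy (adjusted p = 4.51e-11), T follicular helper (1.35e-09), regulatory T cell (1.06e-08), TCR-induced early response (0.000418), inhibitory receptor (0.00193) and negative regulator (0.0461) lists lay higher in D. The ribosomal protein (2.92e-24), MHC class I (4.49e-05) and Ly6 family (7.62e-05) lists and the CD8 T cell marker list (0.0202) lay lower. The Ly6 family list held only 3 measured genes, the sort marker Ly6c1 among them, and the CD8 T cell marker list 1. The negative regulator call was lost without B1 (adjusted p = 0.0547), B3 (0.0520), C1 (0.267), D2 (0.111) or D3 (0.099), the MHC class I call with quantile normalization (0.0541), and the CD8 T cell marker call with the 6 libraries alone (0.0514). None of these held with an estimated correlation, where the adjusted p was 0.367 for the Ly6 family and the CD8 T cell marker, 0.396 for anergy, T follicular helper, regulatory T cell, inhibitory receptors and MHC class I, 0.408 for the early response and ribosomal proteins, and 0.432 for the negative regulators. Among the genes called, the regulatory T cell list shares Ikzf2, Ikzf4, Izumo1r, Nt5e and Tnfrsf18 with the anergy list. The anergy list also shares Nr4a1 and Nr4a3 with the early response, Lag3 and Pdcd1 with inhibitory receptors and Dgkz with negative regulators. Pdcd1 and Cd200 are in both the T follicular helper and inhibitory receptor lists. The early response shares Cd5 with inhibitory receptors, Spry1 with negative regulators and Tnfrsf9 with the regulatory T cell list. These lists are therefore not independent of each other. Jchain and Cd74 were high in C3, one of the 3 libraries of C. With A1 and B1 left out of the fit of all populations, a choice made because of their values and so no independent evidence, 765 genes differed between D and C (506 higher, 259 lower).

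**Figure D4:**
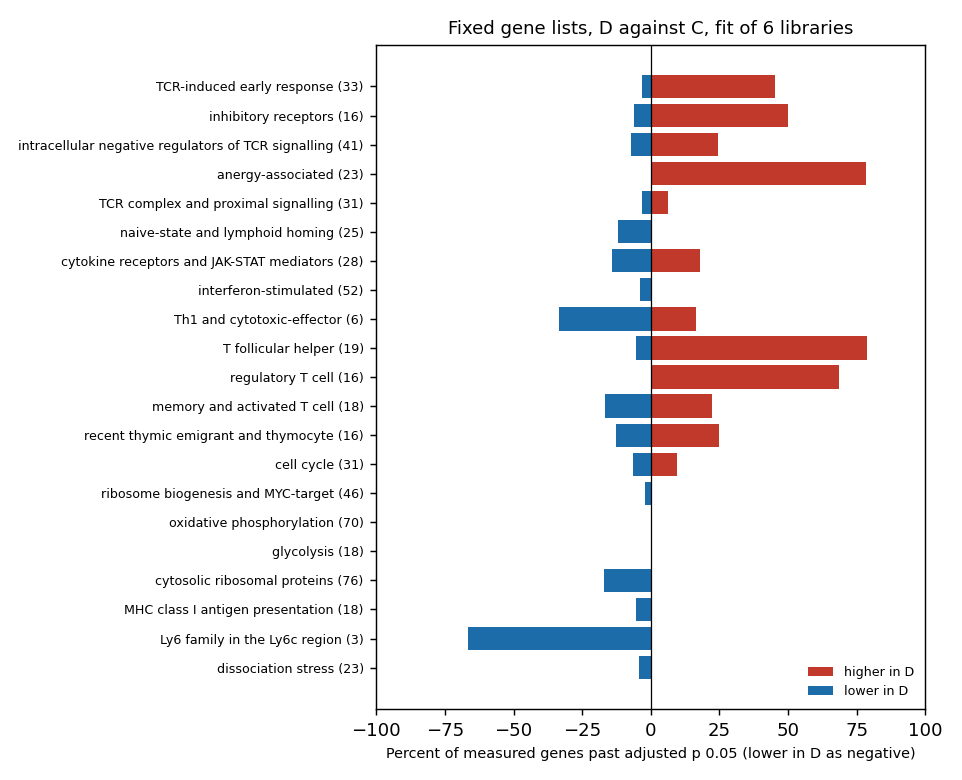
Share of the measured genes of each of the 21 fixed pathway lists (percent; number of measured genes in parentheses) that passed an adjusted p of 0.05 between D and C in the fit of 6 libraries. Bars to the right count genes higher in D and bars to the left genes lower in D. The anergy, T follicular helper and regulatory T cell lists have 18 of 23, 15 of 19 and 11 of 16 genes higher.

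Comparing B with A, GFP intermediate against low among cells labelled Ly6C positive, gave the most calls of any pair in the 12-library fit, with 57 genes higher and 166 lower in B. Dntt fell by 1.09 ± 0.12 on the log2 scale (14.1 ± 1.00 RPKM in A, 6.40 ± 1.31 in B, adjusted p = 0.00791). The next largest decreases were in the zinc finger genes Zfp758 (-1.02 ± 0.16), Zfp935 (-0.90) and Zfp942 (-0.89) and in Gpr34 (-0.97), a receptor for lysophosphatidylserine. Of the genes lower in B, 20 had names beginning with Zfp, against 0 of those higher and 293 of the 9846 tested genes with a GC value, a feature seen after the calls and not tested for enrichment. The largest increases were in Cdk3-ps (0.63 ± 0.14), Zdhhc23 (0.61), Cd6 (0.59), Man2c1os (0.57) and Rhoc (0.56). Man2c1os is named as an antisense transcript and Cdk3-ps as a pseudogene, and whether counting used strand is not given in the sources used here, so both values are uncertain. With the 6 libraries alone, 61 genes were higher and 319 lower. The largest increase there was in the B cell gene Cd79a (0.74 ± 0.14, adjusted p = 0.0333), at 4.27 ± 0.612 RPKM in A and 7.46 ± 1.18 in B, which did not pass with 12 libraries (adjusted p = 0.487). Beside genes already named, Pet100 (0.50), Ager (0.49), Cfp (0.46), Bcl3 (0.46), Naa38 (0.45) and Tmem256 (0.43) were among the 10 largest increases and Snora41 (-0.88), Zfp433 (-0.85), Kbtbd3 (-0.85), Zfp994 (-0.82), Zfp943 (-0.81) and Arhgap5 (-0.81) among the 10 largest decreases. Small nucleolar RNA genes such as Snora41 and Snord104 are as a rule encoded inside other genes, so their values are uncertain. From the fixed lists, the signal-responsive receptor genes Cd5 (0.61) and Cd6 rose, as did the cytokine receptor Il10ra (0.42) and the phosphatase Ptpn7 (0.27), while Klrd1 (-0.81), Ly6c1 (-0.55), Sirt1 (-0.45), Npm1 (-0.26) and Kif23 (-0.54) fell. Nr4a1 had a log2 difference of 0.76 ± 0.30 that did not pass (adjusted p = 0.162). Of the 33 early response genes 1 passed over all genes and 2 when adjusted over the list alone. Of the 23 anergy genes 0 passed as higher and 1 as lower in B in limma, over all genes, over the list alone and with the 6 libraries alone. By camera, the anergy list lay higher in B (adjusted p = 0.0107) and ribosomal proteins lower (0.0357), and neither held with an estimated correlation (adjusted p = 0.873 for both). Without A2, A3, B2 or B3 in turn the adjusted p was 0.103, 0.298, 0.292 and 0.129 for anergy and 0.0633, 0.483, 0.803 and 0.197 for ribosomal proteins, whose median log2 difference was 0.012 without B2. The adjusted p was 0.116 for both with the 6 libraries alone. For ribosomal proteins it was 0.156 with quantile normalization, and 0.0645, 0.0557, 0.0503 and 0.0507 without C1, C3, D1 and D3.

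The B against A calls moved with a measured property of the libraries. Across genes, which are not independent replicates, the difference of B from A correlated with the GC content of the transcript in all 3 mice (r = 0.38, 0.31 and 0.37). Median GC content was 40.2% for genes lower in B, 56.7% for those higher and 49.4% for all tested. With the GC and length trend of each library removed, 3 genes passed. The 3 mice did not move together. Across genes, the B minus A difference of mouse 1 correlated at r = -0.33 with that of mouse 2 and at -0.25 with that of mouse 3, while mice 2 and 3 correlated at 0.77. Fitted with the mouse number as a block, 2 genes passed, the log2 fold changes staying as they were while the adjusted p of Zfp758 went from 0.0367 to 0.0547 and that of Cd5 from 0.0487 to 0.0807. The block and the counts of mice rest on the labelled numbers, and libraries of the same number had a mean correlation of -0.072 across genes in their deviations from the population means. The ribosomal protein list also lost its call under the block (adjusted p = 0.0693). In fits without the block, the count was 237 without A1 (113 higher, 124 lower) and 222 without B1 (119 higher, 103 lower). It was 0 without A2, 2 without A3, and 0 without B2 or B3. With 1 library of C or D left out it was 461 without C1 or C3, 63 without C2, 166 without D1, 2 without D2 and 68 without D3. With A1 and B1 left out because of their values, 1094 genes passed, 667 higher and 427 lower, and the anergy list had 18 of its 23 genes higher in B and 1 lower, against 0 and 1 with them in.

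Comparing D with A sets the ends of the sort against each other. Dntt again was the gene that passed in the 12-library fit and fell by 1.25 ± 0.12 on the log2 scale (adjusted p = 0.00187), with the same sign in all 3 mice, and 1905 genes lay at an unadjusted p under 0.05. Cd5, whose protein tracks TCR signal strength, was 191 ± 44.0 RPKM in A and 310 ± 11.4 in D, a log2 difference of 0.72 ± 0.14 that did not pass (adjusted p = 0.151). Nr4a1 (0.96 ± 0.30, adjusted p = 0.169) and Ly6c1 (-0.56 ± 0.12, 0.151) did not pass either. Fitted on 6 libraries alone, 3 genes passed, with Dap (0.47) and Klrd1 (-0.75), a killer cell lectin receptor, beside Dntt. Adjusted over the list alone, 16 of 23 anergy genes were higher and 1 lower, and 5 of 33 early response genes were higher and 1 lower. Camera placed, among others, the anergy (adjusted p = 4.33e-07), regulatory T cell (1.23e-05), T follicular helper (0.000315) and early response (0.000463) lists higher in D and the ribosomal proteins lower (3.38e-05), the last not called with quantile normalization (0.162). With an estimated correlation the adjusted p was 0.584 for anergy, regulatory T cell and early response, 0.688 for T follicular helper and 0.711 for ribosomal proteins. The CD8 T cell marker list lay lower (0.0385) and lost that call with an estimated correlation (0.584), with the mouse number as a block (adjusted p = 0.0563), with quantile normalization (0.0551), with limma-voom (0.0654) and without A1 (0.0742), A3 (0.0708), C1 (0.0525) or D1 (0.105). Without A1, 362 genes passed, and without A1 and B1 886 did (609 higher, 277 lower). That last fit was chosen because of the values of A1 and B1, which stood apart in Nr4a1 itself. Its differences and their small SE are therefore no independent evidence, and genes were named from it after their values were seen. In it Tnfrsf9 (log2 fold change 3.39 ± 0.15), Eomes (3.62 ± 0.14), Lag3 (3.37 ± 0.28) and Nr4a1 (1.36 ± 0.10) were higher and Igfbp4 (-0.75 ± 0.06) and Il7r (-0.98 ± 0.09) lower in D.

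Comparing C with B, both labelled GFP intermediate, sets Ly6C negative against positive by label, though Nr4a1 was higher in B than in C in 3 of 3 mice. Dntt was higher in C by 1.01 ± 0.12 on the log2 scale (adjusted p = 0.0187), and no other gene passed in the 12-library fit, with 1342 at an unadjusted p under 0.05. Dntt did not pass with the 6 libraries alone or without B2, B3, D1 or any library of C, where the count of genes was 0 each time. Ly6c1, which the gates would place lower in C, had a log2 difference of 0.55 ± 0.12 (adjusted p = 0.271), and Nr4a1 one of -1.08 ± 0.30 (0.285). Adjusted over the list alone, 12 of 23 anergy genes and 10 of 19 T follicular helper genes were lower in C, and 0 and 1 were higher. Camera placed, among others, the anergy (adjusted p = 2.59e-08), T follicular helper (1.09e-06) and regulatory T cell (1.49e-05) lists lower in C and the ribosomal proteins (4.93e-23), oxidative phosphorylation (0.000867) and Ly6 family (7.07e-05) lists higher. With an estimated correlation the adjusted p was 0.293 for the Ly6 family and 0.406 for the others. Lists of other cells and of sample handling also lay higher in C, the CD8 T cell marker (adjusted p = 0.0131), myeloid (0.0291) and dissociation stress (0.0279) lists. With an estimated correlation these stood at 0.293, 0.406 and 0.676. The myeloid call was lost without B1 (0.115), B3 (0.0649) or C3 (0.387) and with a filter of 5 RPKM (0.0776), and the stress call without B3 (0.460) or C3 (0.651) and with quantile normalization (0.144). The oxidative phosphorylation call was also lost without C3 (0.0668), and with the GC and length trend removed its median log2 difference went from 0.059 to -0.0019 (adjusted p = 0.934). The count was 386 without B1 and 776 without A1 and B1 (277 higher, 499 lower in C).

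Between C and A, 0 genes passed in limma (1422 at an unadjusted p under 0.05, smallest adjusted p = 0.204), and between D and B 0 passed (410 at an unadjusted p under 0.05, smallest adjusted p = 0.958). With limma-voom on recovered reads both counts were also 0. Nr4a1 differed by -0.32 ± 0.30 between C and A and by 0.20 ± 0.30 between D and B. Leaving out C1 gave 322 genes between C and A, 34 higher and 288 lower in C. The deviations of C1 from the gene means correlated with GC content at r = -0.21 across genes, against 0.23 in C2 and 0.16 in C3. In A1, A2 and A3 the values were -0.37, -0.36 and -0.4. Without C1, the correlation was thus negative in every library of A and positive in those of C. The counts without C1 were not refitted with the GC trend removed, so its part in them was not tested. By camera, ribosomal proteins (adjusted p = 8.77e-10), oxidative phosphorylation (0.0150) and MHC class I genes (0.00639) lay higher and T follicular helper genes lower (0.0113) in C than in A, with an adjusted p of 0.935 for each with an estimated correlation. Without A1 the T follicular helper median was -0.012 in place of -0.24 (adjusted p = 0.733) and the MHC class I call was lost (0.129), as was that of oxidative phosphorylation without A3 (0.140) or C3 (0.184). With quantile normalization the ribosomal (0.355), oxidative phosphorylation (0.110) and MHC class I (0.248) calls were lost, the last 2 also with the GC and length trend removed (0.640 and 0.587). Between D and B the anergy (0.00505), T follicular helper (0.00449), regulatory T cell (0.00449) and oxidative phosphorylation (3.98e-05) lists lay higher in D and MHC class I lower (0.000772). With an estimated correlation the adjusted p was 0.930 for oxidative phosphorylation and MHC class I and 0.934 for the others. Without B1 the median log2 difference of D from B went from 0.23 to -0.044 for anergy (adjusted p = 0.866), from 0.28 to 0.026 for T follicular helper (0.986) and from 0.30 to -0.054 for regulatory T cell genes (0.986), and the MHC class I call was lost (0.239). The regulatory T cell call was also lost without D3 (0.0505). The test of whether the D minus C step differs from the B minus A step gave 0 genes in limma (1507 at an unadjusted p under 0.05, smallest adjusted p = 0.168) and 0 in limma-voom, and 261 without C1. The smallest p values were those of Abracl (log2 difference 0.48 ± 0.08) and Zc3h15 (0.38 ± 0.06) among positive and of Setd4 (-0.45 ± 0.09) and Srm (-0.56 ± 0.11) among negative differences, none past the threshold. Over all 4 populations, the F test gave 1 gene, Dntt (adjusted p = 0.00135), with 154, 401 and 113 genes without A1, B1 and C1.

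Most markers of other cell types were not among the genes tested, and the rule by which the deposited table lists genes is not given in the sources used here. Of the fixed lists, 3 of 22 B cell, 5 of 19 myeloid, 3 of 11 dendritic cell, 1 of 2 CD8 T cell, 4 of 20 NK, NKT and gamma-delta T cell, 3 of 11 erythroid and platelet and 1 of 10 stroma and endothelium markers were measured. The CD8 T cell marker measured, Cd8b1, was lower in D than in C in the fit of 6 libraries (-0.44 ± 0.09, adjusted p = 0.0354). In the NK list, Il2rb and Cd160 (0.77) were among the genes higher in D than in C in that fit, and none was lower. In that limma fit 0 B cell, myeloid, dendritic, erythroid or stromal markers passed, with C3 standing apart on the first 3 of these lists. Its mean log2(RPKM + 0.5) was 4.77 over the B cell markers against 1.27 to 2.53 in the other libraries, 3.85 against 3.12 to 3.29 over the myeloid and 3.25 against 1.84 to 2.34 over the dendritic cell markers. Between B and A, the B cell marker Cd79a was higher in B with the 6 libraries alone. The haemoglobin gene Hbb-bs was low in A1 (6.98 RPKM), B1 (13.99), C2 (4.78) and D2 (12.7) and between 79.1 and 110.6 RPKM in the other 8 libraries, a division that does not follow the labelled mice.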

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

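Leaving out each library of the populations not compared, leaving out A1 and B1, leaving out A1, B1 and C3, limma-voom on recovered reads and removing the GC and length trend were chosen after the results were seen, those without A1 and B1 because of these libraries' own values, so that their counts are not independent evidence. The counts rested most on which libraries entered. With the 6 libraries compared alone, 3 genes passed between D and A, 380 between B and A, 0 between C and B (limma) and 481 between D and C. Without A1 and B1 the counts were 886, 1094, 776 and 765, and 965 over the 4 populations. Without A1, B1 and C3 they were 1357, 1638, 873, 841 and 1311. Leaving out 1 library of the populations compared at a time gave 1 to 362 genes between D and A (362 without A1), 0 to 237 between B and A (0 without A2, B2 or B3 and 2 without A3), 0 to 386 between C and B (386 without B1), 1 between D and C without any library of C or D, 0 to 322 between C and A and 0 to 261 for the difference of steps (both highest without C1), and 1 to 401 over the 4 populations (401, 154 and 113 without B1, A1 and C1, and 2 without D3). Leaving out 1 library of the other populations gave 288 genes between D and C without A1, 398 without B1 and 1 without the other 4, between B and A 461 without C1 or C3, 63 without C2, 166 without D1, 2 without D2 and 68 without D3, between C and B 0 in limma without D1 and 1 otherwise, 1 between D and A, and 0 in limma between C and A and between D and B. Between B and A, 2 genes passed with the mouse number as a replicate block, fixed or random, 3 without the trend, 3 at an absolute log2 fold change of at least 1, and 3 with the GC and length trend removed. Apart from the removal of that trend, after which the differences were smaller, the cause of each loss was not tested. Of the 223 genes, 184 were kept with 6 libraries and 186 without A1 and B1. The block rests on the labelled mouse numbers, which may not stand for animals, as the check of pairing gave a mean correlation of -0.072. The block, fixed or random, changed no other gene count. Beyond the B against A genes, the fixed block changed only the list calls for ribosomal proteins (B and A) and the CD8 T cell marker (D and A). Lists were not tested with the random block. Limma-voom gave 2 genes over the 4 populations. Of 47 list calls by camera, 0 held with an estimated correlation. Fry, which tests a list against no change and not against other genes, called 4 of them. The camera count was 40 to 57 with 1 library left out. The other settings gave between 221 and 317 genes for B and A, and those counts stayed within 1.5 times the reported one.

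Some values changed direction. With 1 library left out, the log2 difference of Cd44 between D and A ran from -0.059 to 0.076 and of Nr4a1 from -0.57 to 0.084 between C and A and from -0.11 to 0.40 between D and B. List medians ran from -0.044 to 0.39 (anergy, D and B), -0.054 to 0.50 (regulatory T cell, D and B) and -0.12 to 0.012 (ribosomal proteins, B and A). Without A1 and B1, and also without C3, Cd44 was 0.0069 between B and A, Nr4a1 -0.11 and the 2 list medians -0.044 and -0.054 between D and B. Nr4a1 between C and A was 0.084 without A1 and B1 and 0.16 without C3 as well. With the GC and length trend removed, oxidative phosphorylation between C and B was -0.0019. The cause was not tested. Planned count-model tests were not run, and the F test has no fold change limit.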

Other observations

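Between D and C, members of further fixed lists also passed in the fit of 6 libraries. Of 16 recent thymic emigrant and thymocyte genes, 4 were higher in D, among them the transcription factors Sox4 (log2 fold change 1.83) and Tox (0.84), and 2 were lower, Dntt and Cd8b1. The T-box factor Eomes (3.56) was higher while the cytotoxic genes Prf1 (-0.43), which encodes perforin, and Ctsw (-0.32) were lower. Of 18 memory and activation genes, 4 were higher, including Il2rb (1.95) and Maf (1.40), and 3 lower, including Vim (-0.38). Of 31 TCR complex and proximal signalling genes, the costimulatory receptor Cd28 (0.49) and the kinase Fyn (0.31) were higher and the adaptor Grap2 (-0.24) lower. Of 31 cell cycle genes, 3 were higher, including Stmn1 (0.70) and Cenpa (0.57), and 2 lower, including Kif23 (-0.55). The mean level of that list, in log2(RPKM + 0.5), was 3.43 in C3 against 2.73 in C1, 2.65 in C2 and 2.96 to 3.16 in D, and 12 of its genes were higher in D with A1, B1 and C3 left out, against 5 with A1 and B1 left out. Of 52 interferon-stimulated genes Ly6a (-0.58) and Gbp2 (-0.24) were lower, and single genes were lower among 18 MHC class I (Psmb9, -0.25), 46 ribosome biogenesis (Rrp12, -0.29) and 23 dissociation stress genes (Socs3, -0.43). Camera on 12 libraries called none of these lists but MHC class I, a call lost with an estimated correlation (adjusted p = 0.396) and with quantile normalization (0.0541). For the others it gave adjusted p = 0.981 for thymocyte, 0.981 for cytotoxic, 0.614 for memory, 0.173 for TCR complex, 0.125 for cell cycle, 0.198 for interferon, 0.0776 for ribosome biogenesis and 0.0594 for stress.

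All tests in the next 2 paragraphs were chosen after the results were seen. Transcripts of the sort markers followed the labelled gates in part. By labelled mouse number, Nr4a1 was higher in D than in C and than in A, and Ly6c1 higher in A than in D, in 3 of 3 mice, while Ly6c1 was higher in C than in B in 3 of 3 and Nr4a1 higher in A than in B in 1 of 3. A1 and B1 lay opposite to the other libraries of their populations. Libraries labelled A otherwise lay with C and those labelled B with D, a pairing that neither gate gives as labelled. The Ly6C gate would give that pairing if the headings B and C were exchanged, which was not tested. Ly6c1 was higher in A and in C than in B and in D in 3 of 3 mice. With A1 and B1 left out, 0 genes passed in limma between C and A and between D and B. In that fit 765 passed between D and C and 1094 between B and A. The GC trend of B minus A had the same sign in mouse 1 (r = 0.38 across genes) as in mice 2 and 3 (0.31 and 0.37). That cannot decide on an exchange of the A1 and B1 columns after library preparation, because in C and D the trend did not follow the population. The deviations of single libraries from the gene means correlated with GC content at -0.21 in C1 but 0.23 in C2 and 0.16 in C3. In D1, D2 and D3 the values were -0.2, 0.14 and 0.22. An exchange of cells before library preparation stays open, because 37 of 40 genes that differed by at least 1 on the log2 scale in mice 2 and 3 were reversed in mouse 1, with a median ratio of -0.73 (interquartile range -0.87 to -0.54), while Dntt, Zfp758 and Arhgap5 kept their direction. Among genes that differed by at least 0.5 the picture was less clear, with 132 of 182 reversed, a median ratio of -0.44 (interquartile range -0.74 to 0.10), and 50 kept, Ly6c1 and Cd6 among them. With the GC and length trend removed, 124 of 142 such genes were reversed, with a median ratio of -0.63 (interquartile range -0.86 to -0.31) and 18 kept. Whether headings more widely, those of B and C among them, follow neither animals nor gates stays open. Exchanging B and C within each mouse would leave the mouse numbers unchanged, so partitions by mouse number cannot decide on it. With 3 components removed, 53 of 100 partitions of the libraries into 3 sets of 4, the labelled mouse numbers included, gave at least as many genes at an F test p under 1e-04 as the mouse numbers did (1, highest other 5), counts too near 0 to separate partitions. Hbb-bs and Erdr1, picked after their values were seen, parted A1, B1, C2 and D2 from the other 8 libraries, 1 library of each population and across mouse numbers. For these 2 genes libraries of the same population differed, and nothing further is drawn from genes picked this way. Whether that division is by animal was not tested. A biological cause, such as reporter protein and transcript differing in the sorted cells, was not tested.

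The 223 genes called between B and A were mostly lower in B. That excess depended on single libraries, with 113 higher and 124 lower without A1 and 119 higher and 103 lower without B1. A trend in GC content between libraries is a candidate explanation, as 3 genes passed once it was removed together with a length trend. Among the 219 calls with a GC value, the median log2 fold change in the called direction went from 0.353 to 0.191 and the median SE from 0.076 to 0.062, so the calls ended because the differences shrank, and 1 of the 219 was kept. A trend with gene length has little room, its largest correlation with B minus A being 0.06 in absolute size, and the depths overlapped (mean 7.75 M reads in A and 7.64 in B). A difference between the cells of A and B stays open and was not tested apart from the GC trend, which ran between the same libraries.

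Other groupings of the same libraries were compared with the labelled one, in tests planned before the data were examined except those on 6 libraries alone. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave 1 gene between D and A (highest other split 0; 1 of 10 as large), 223 between B and A (606; 2 of 10), 1 between C and B (4; 2 of 10), 1 between D and C (0; 1 of 10), 0 in limma between C and A (0; 10 of 10) and 0 between D and B (0; 10 of 10). Fitted on 6 libraries, it gave 481 between D and C (0; 1 of 10) and 380 between B and A (440; 2 of 10). The split with 606 and 440 genes exchanges A1 with B1. Of the 4 splits that part all 3 mice, it and the labelled one gave these counts and the other 2 gave 0 genes in both limma fits, so parting the mice does not set the high counts apart. The 606 genes point to a structure of the samples. Over 12 libraries, the 100 splits were drawn without regard to mouse, and splits within mice were not drawn. Of these, 4 of 100 gave as many genes in the F test as the labelled one (1, highest other 880). The draws ignored the mouse and the count was 1 gene, so that share does not decide on chance. The 880 genes again point to structure. For the difference of steps, 100 of 100 gave as many (0, highest other 1493). With a labelled count of 0 no split can give fewer, so that share decides nothing. For the lists, 42 of 100 gave as many (47 calls, highest other 72), so chance is not excluded there.

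The gene Erdr1, named after its values were seen, was at 30.4 RPKM in A1, 38.6 in B1, 40.1 in C2 and 33.2 in D2 and between 64.2 and 76.5 in the other 8 libraries, the same division as for Hbb-bs. C3 also held 37.4 RPKM of the B cell gene Cd79a, against 3.57 to 8.80 in the other 11 libraries.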
